A study of Homo sapiens with 9 samples.

How the data were processed

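RNA from 9 samples of HK2 cells was hybridised to 9 Agilent one-colour arrays, 3 each for sham, vehicle OGD and enarodustat OGD. Per the file headers, the intensity values come from Agilent Feature Extraction 11.5.1.1, which found the spots, subtracted a background and wrote a processed signal for each spot, with probe coordinates on hg19. The deposited flags, also made by Feature Extraction per the file headers, are 0 or 1 for each spot and mark outliers, saturation and signal well above background. The series table holds log2 values deposited by the authors, who name limma among their tools without a version. Its columns correlated at r = 0.9998 to 0.9999 with log2 values made here by normexp correction (offset 50) and quantile normalization, with median differences of 0.013 to 0.014, and at 0.902 to 0.924 with the log2 processed signal. The amount and purity of RNA on each array were not in the sources used.

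All values were computed from the scanner files with R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Control spots were left out, as were 592 spots marked as outliers over all arrays and 19 probes left with no usable spot on an array. Spots of 1 probe were averaged as log2, which gave 58201 probes before those 19 were removed. Each array was scaled by subtracting the 75th percentile of its log2 processed signals. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 30215 probes, 24479 of them above background on all 9 arrays. A gene with several kept probes was represented by the probe with the highest mean over the 9 arrays, which gave 23278 genes, 19095 of them above background on all 9 arrays. The number of arrays limits the precision. The median residual SD of a gene was 0.121 (log2).

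Gene names came from the files and were updated with a table of RefSeq names of GRCh38.p14, used for names only. Probes were matched by accession (31104), symbol (3366) or a synonym with 1 meaning (496), and 23235 kept the name in the file. Of the tested genes, 1522 names were updated, and 23 symbols were shared by 2 tested names.

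The 3 comparisons were vehicle OGD against sham, enarodustat OGD against vehicle OGD, and enarodustat OGD against sham. Each was a contrast of group means in a limma model of all 9 arrays (lmFit and eBayes, two-sided). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes were called, and the number also changed at least 2-fold is given beside them. The SE is the moderated standard error. A gene above background on every array of only 1 of the groups compared is given as a bound on its fold. These comparisons, the tests, 37 gene lists with 686 genes, the genes to be named and most alternatives were chosen before the data were examined. Of the list genes, 625 were measured, and the 34 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance 1 way without comparing it with other genes, were run beside it. With fry 31, 24 and 31 lists passed in the 3 comparisons, in that order. For each list the genes called are given adjusted over all genes and adjusted over the list alone.

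The genes named for each comparison are the 8 with the largest rise and the 8 with the largest fall among called genes above background on every array of both groups and without overlap between groups. They also include the 3 largest bounds in each direction, up to 4 members of a list described in the text with the largest moderated statistic, and 18 genes named always, 12 of which are in the plot of signals per array. Names that are not symbols of known genes were passed over. Some list members that this would name are not reported here. PFKM, NEAT1, MALAT1, KLF3 and PCF11, and further small RNAs given as classes, were chosen after their values were seen.

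The model was tested on simulated data with 200 changed genes among 23278, built from the spread of these arrays. At changes of 1.5, 2 and 4-fold it recovered 56.7, 94.0 and 100% in vehicle OGD against sham, with 9 false calls of 176. In enarodustat OGD against vehicle OGD it recovered 53.7, 85.1 and 97.0%, with 2 false calls of 159, and in enarodustat OGD against sham 53.7, 86.6 and 100%, with 14 false calls of 174. The simulated values had independent noise, far fewer changed genes than were called on the real arrays, and no scaling step. These rates therefore do not cover errors from the scaling. A list shifted by 0.5 (log2) was called, and 0 other lists were. This outcome does not show how often camera calls lists falsely on these arrays. The list shifted was glycolysis, whose estimated correlation on the real arrays was 0.26, against the preset 0.01. When the real arrays were split into other groups, up to 8 lists were called in vehicle OGD against sham. Up to 7 were called in enarodustat OGD against vehicle OGD, and up to 14 in enarodustat OGD against sham. These other splits mix the 2 real groups unevenly and so keep part of the real difference. Their counts are therefore not a rate of false calls.

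The alternatives were quantile, median and spike-in scaling, normexp correction, the authors' series table, no filter on dim probes or a filter on all 9 arrays, the mean of a gene's probes, every probe on its own, a trended and robust prior, array weights, the replicate number as a block, a model of only the 6 arrays compared, and leaving out each array in turn. Taking the probe nearest the 3′ or the 5′ end, testing protein-coding genes only, and leaving out probes with AG runs were added after the data were seen. The correlation of 2 comparisons that share arrays was set beside 100 simulations of 3 unchanged groups. Random lists (10000) were matched to a list by signal level. The slide could not be used as a block, because 1 slide held all enarodustat OGD arrays and no others.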

Results

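Transcript levels were measured in HK2 cells, an immortalised human renal proximal tubule line, on 9 Agilent one-colour microarrays, 3 per group. Sham cells were kept in DMSO for 24 h and then in normal medium for 16 h. Vehicle OGD cells were kept in DMSO for 24 h and then went through 16 h of oxygen-glucose deprivation (OGD), in an anoxic bag and in medium lacking glucose and serum. Enarodustat OGD cells received 10 µM enarodustat for 24 h before the same deprivation. Enarodustat inhibits the prolyl hydroxylases (PHD) that mark hypoxia-inducible factor (HIF) for degradation. The labels do not say whether the drug stayed on during the deprivation, or whether the samples of a group were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

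Each array held 62976 spots. The 75th percentile of the processed signal was 136 to 144 on the sham arrays, 50.1 to 62.9 on the vehicle OGD arrays and 83.9 to 85.0 on the enarodustat OGD arrays. The share of spots above background was 55.2 to 55.3% in sham, 48.2 to 48.9% in vehicle OGD and 50.4 to 52.0% in enarodustat OGD. The 100 brightest spots held 16.6 to 16.8% of the summed signal in sham, 22.2 to 24.5% in vehicle OGD and 19.8 to 20.3% in enarodustat OGD. No spot was saturated. Relative to 7 spike-in probes, the 75th percentile was −4.47 ± 0.02 (log2, SD, n = 3) in sham, −5.84 ± 0.04 in vehicle OGD and −5.44 ± 0.06 in enarodustat OGD, which is 2.58-fold and 1.96-fold lower than sham. Across genes, arrays of 1 group correlated at r = 0.988 to 0.997 and arrays of different groups at 0.940 to 0.983, with genes not being independent replicates. The number of arrays limits the precision. The sham and vehicle OGD arrays lay on 1 slide and the enarodustat OGD arrays on another, so slide and enarodustat cannot be told apart by the design in any comparison that holds the drug. The 7 spike-in probes were 0.07 to 0.24 higher (log2, unscaled) in enarodustat OGD than in vehicle OGD.

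Changes below are log2 fold changes ± SE from limma with n = 3 arrays per group, relative to each array's 75th percentile, and probe coordinates are on hg19. Scaling by the spike-ins instead placed the median of all genes at −1.46 for vehicle OGD against sham, 0.42 for enarodustat OGD against vehicle OGD and −0.98 for enarodustat OGD against sham. The changes of gene groups are therefore given relative to the median of all genes, and a gene whose own direction turned with that scaling is named with it. Spike-in scaling leaves the shift of a list from all genes unchanged. It does change the moderated statistics that camera tests, so a list can lose or turn its call with its shift unchanged. Of 37 gene lists fixed in advance, 34 had at least 5 measured genes and were tested with limma's camera at a preset correlation. No list call in any comparison held with an estimated correlation, where the lowest adjusted p was 0.371, 0.115 and 0.228 for the 3 comparisons in the order above. Where a gene was above background in 1 group only, the text gives a bound, written as at least N-fold.

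Vehicle OGD was compared with sham to see what deprivation alone did. HIF targets as a list stood higher relative to all genes in deprived cells, with 18 of 33 above sham and 7 below. ADM, which encodes the vasodilator peptide adrenomedullin, was higher by 3.90 ± 0.06 (14.9-fold, adjusted p = 4.01e-08; chromosome 11, 10328780 to 10328839). Histone genes were also higher, with H2BC21 at 2.64 ± 0.09 (adjusted p = 4.71e-07). Genes of DNA replication were lower, with 24 of 26 below sham, and EGR1, an immediate early transcription factor, fell by 4.53 ± 0.18 (23.1-fold, adjusted p = 6.59e-07; chromosome 5, 137804891 to 137804950).

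Among HIF targets outside glycolysis, 18 of 33 measured genes rose and 7 fell, the same counts as adjusted over the list alone. The list stood 0.57 above the median of all genes (adjusted p = 0.00528, and adjusted p = 0.410 with an estimated correlation). HILPDA, a lipid droplet protein, was higher by 3.24 ± 0.07 (adjusted p = 9.67e-08), DDIT4, an inhibitor of mTORC1 signalling, by 2.51 ± 0.09 (adjusted p = 5.05e-07), and ANKRD37 by 1.79 ± 0.07 (adjusted p = 5.97e-07). VEGFA, the vascular growth factor, was higher by 1.51 ± 0.08 (adjusted p = 1.74e-06), but by 0.14 with spike-in scaling, where its call was lost (adjusted p = 0.108), and its other probe was at 0.44. BNIP3, a mitophagy receptor, rose by 0.34 ± 0.06 (adjusted p = 0.000843) but stood at −1.03 with spike-in scaling. EGLN3, the PHD enzyme that HIF itself induces, was at −0.24 ± 0.13 (adjusted p = 0.119), and CA9, carbonic anhydrase 9, was above background in neither group. Without a filter on dim probes the list no longer passed. With spike-in scaling its median was −0.88, with 7 genes above sham and 21 below.

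Glycolysis genes moved both ways. Of 21 measured, 6 rose and 11 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.728, and 0.874 with an estimated correlation), with its median at −0.27 and its mean at 0.02. SLC2A3 and SLC2A1, glucose transporters, were higher by 1.78 ± 0.11 (adjusted p = 3.57e-06) and 0.41 ± 0.06 (adjusted p = 0.000583). The enzymes hexokinase 2 (HK2) and enolase 2 (ENO2) were higher by 1.58 ± 0.12 and 1.12 ± 0.09 (adjusted p = 1.16e-05 and 1.31e-05), and HK2, whose other probe was at 2.51, lost its call with spike-in scaling (0.21, adjusted p = 0.0958). PDK1, which inhibits pyruvate dehydrogenase, rose by 0.47 ± 0.07 and PFKFB4, a regulator of glycolytic flux, by 0.61 ± 0.07 (adjusted p = 0.000305 and 7.30e-05). With spike-in scaling, ENO2 (−0.25), SLC2A1 (−0.96), PDK1 (−0.90) and PFKFB4 (−0.75) were below sham. PGAM1 and LDHA, a mutase and the lactate dehydrogenase of this pathway, fell by 0.88 ± 0.05 and 0.33 ± 0.08 (adjusted p = 3.16e-06 and 0.00626). Of 22 glycogen genes, 6 rose and 11 fell, or 7 and 12 adjusted over the list alone, without passing (adjusted p = 0.609, and 0.744 with an estimated correlation). PPP1R3C, a glycogen-targeting phosphatase subunit, rose by 1.45 ± 0.06 (adjusted p = 9.12e-07), a call lost with spike-in scaling (0.08, adjusted p = 0.265), while glycogen synthase GYS1 and the branching enzyme GBE1 fell by 0.53 ± 0.06 and 0.78 ± 0.07 (adjusted p = 8.64e-05 and 2.70e-05).

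Histones rose as a group, with 11 of 15 genes higher and 2 lower, or 12 and 2 adjusted over the list alone, 0.87 above all genes (adjusted p = 0.00242, and 0.371 with an estimated correlation). With spike-in scaling their median was −0.58, with 3 higher and 10 lower. H2BC5 was higher by 1.74 ± 0.05 (adjusted p = 2.48e-07). NF-kB signalling genes had 11 of 19 higher and 5 lower, also adjusted over the list alone, 0.55 above all genes (adjusted p = 0.0417, and 0.493 with an estimated correlation). The call was lost with spike-in scaling, where camera's direction was down (adjusted p = 0.691) and 1 gene was above sham and 18 below. The shift from all genes stayed at 0.55 with that scaling. The call was also lost without sham 1 or vehicle OGD 1 (adjusted p = 0.0520 and 0.0506) and under 4 other alternatives. TNFAIP3, an inhibitor of NF-kB, was higher by 2.0 ± 0.06 (adjusted p = 2.33e-07). BIRC3, an inhibitor of apoptosis, was higher by 1.12 ± 0.08 (adjusted p = 1.04e-05) and at −0.25 with spike-in scaling. NFKBIZ, a nuclear co-regulator of NF-kB, fell by 0.99 ± 0.08 (adjusted p = 1.79e-05). Genes of the G1/S phase and DNA replication had 24 of 26 lower and 0 higher, or 25 lower adjusted over the list alone, 0.50 below all genes (adjusted p = 6.50e-05, and 0.371 with an estimated correlation). CDT1, a replication licensing factor, fell by 1.12 ± 0.06 (adjusted p = 2.22e-06), CCNE2, cyclin E2, by 0.71 ± 0.05 and PCNA, the polymerase clamp, by 0.68 ± 0.06. CCNE2 lost its call at the probe nearest the 5′ end (−0.16, adjusted p = 0.230).

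**Figure D1:**
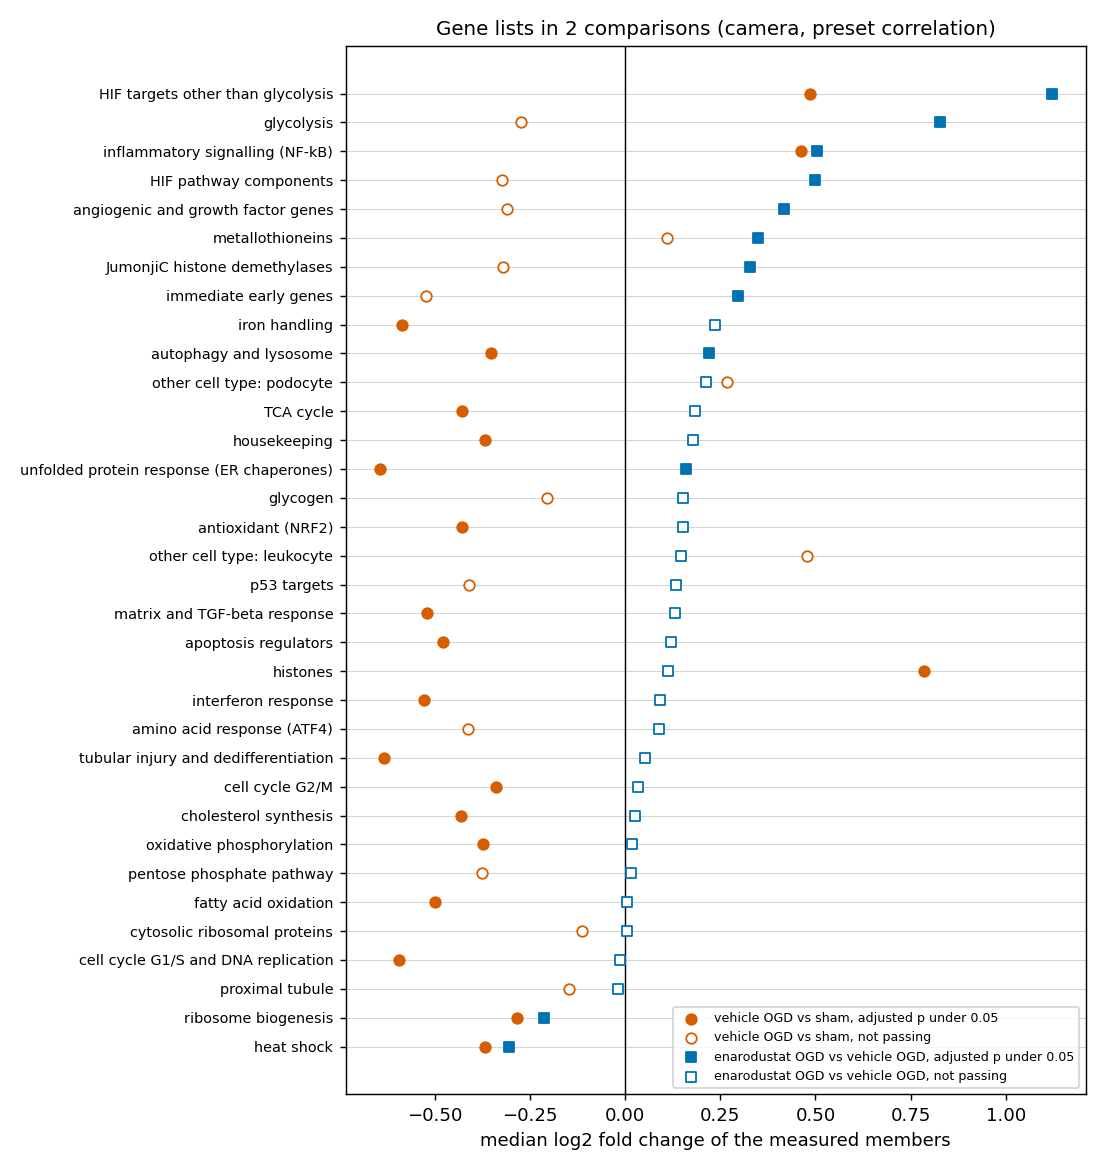
Median log2 fold change of the measured genes of each of 34 lists, relative to the 75th percentile, for vehicle OGD against sham (circles) and enarodustat OGD against vehicle OGD (squares), filled where the list passed camera at the preset correlation and open where it did not. HIF targets lie at 0.49 and 1.12 and glycolysis at −0.27 and 0.83, and spike-in scaling, which puts the median of all genes at −1.46 and 0.42, would place HIF targets and every other list below 0 in the first comparison.

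A further 16 lists lay below all genes, and their calls depended on the genes they were compared with and, for most, on the normalization. In mitochondrial metabolism, 25 of 35 oxidative phosphorylation genes fell and 2 rose, 16 of 19 tricarboxylic acid cycle genes fell and 1 rose, and 16 of 20 fatty acid oxidation genes fell and 2 rose. Examples are ATP5F1A, a subunit of ATP synthase, at −0.92 ± 0.09, UQCRFS1, a subunit of complex III, at −0.62 ± 0.05, MDH2, malate dehydrogenase, at −0.60 ± 0.07, SUCLA2, a succinate-CoA ligase subunit, at −0.56 ± 0.06, CPT2, a carnitine palmitoyltransferase, at −1.07 ± 0.10, and HADH, at −0.87 ± 0.07. In cholesterol synthesis 19 of 24 fell and 1 rose. In the unfolded protein response 15 of 20 fell and 1 rose, with XBP1, its transcription factor, at −1.55 ± 0.05 and the chaperone HSPA5 at −1.18 ± 0.07. In the heat shock list 10 of 13 fell and 1 rose, with the co-chaperones DNAJA1 at −1.70 ± 0.05 and DNAJB1 at −1.68 ± 0.08. In the interferon response 19 of 22 fell and 1 rose, with IFI44L at −1.70 ± 0.07 and ISG20, an exonuclease, at −0.92 ± 0.05.

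Of the remaining lists among these 16, 20 of 25 G2/M genes fell and 2 rose, and 17 of 25 ribosome biogenesis genes fell and 2 rose. In the list of tubular injury and dedifferentiation 11 of 15 fell and 1 rose, with PAX8 at −1.09 ± 0.05, SOX4 at −1.94 ± 0.14 and LCN2 at −1.27 ± 0.09. HAVCR1, the injury marker KIM-1, was at −0.69 ± 0.07. In iron handling 9 of 12 fell and 1 rose, with the transferrin receptor TFRC at −1.79 ± 0.07, and in NRF2 antioxidant genes 15 of 19 fell and 2 rose, with AKR1C3 at −1.60 ± 0.08, GCLC, of glutathione synthesis, at −1.04 ± 0.08 and HMOX1, heme oxygenase 1, at −0.56 ± 0.13, a call lost with quantile normalization (−0.27, adjusted p = 0.106) and normexp (−0.24, adjusted p = 0.0521). In autophagy and lysosome genes 19 of 26 fell and 5 rose, in apoptosis regulators 15 of 21 fell and 3 rose, and in the housekeeping list 10 of 14 fell and 2 rose. In matrix and TGF-beta response 14 of 22 fell and 4 rose, with ID3, a target of BMP signalling, at −2.41 ± 0.09 and collagen COL1A1 at −1.52 ± 0.07. All genes named in these 16 lists had adjusted p of at most 0.00461. Adjusted over the list alone, the counts were the same except in the tricarboxylic acid cycle (17 lower), G2/M (3 higher), apoptosis regulators (16 lower) and iron handling (2 higher). These lists passed with adjusted p from 0.00411 to 0.0460, against adjusted p from 0.371 to 0.497 with an estimated correlation. Set against protein-coding genes alone, all 16 lost the call (adjusted p = 0.188 to 0.469). With spike-in scaling heat shock, NRF2, apoptosis and iron genes lost it too (adjusted p = 0.0783, 0.0682, 0.0604 and 0.104). With quantile normalization 11 of the 16 lost it, all but the unfolded protein response, heat shock, interferon, NRF2 and housekeeping lists (adjusted p = 0.0520 to 0.653), with oxidative phosphorylation then only 0.05 below all genes and G2/M 0.00 below. Of these 11, all but iron handling also lost it with normexp and quantile normalization (adjusted p = 0.0823 to 0.594) and with the series table (adjusted p = 0.0649 to 0.683). With a filter on all 9 arrays 9 lost it (adjusted p = 0.0541 to 0.0736), and 4 lost it at the probes nearest the 3′ end (adjusted p = 0.0536 to 0.170). The probes nearest the 5′ end ended it for apoptosis and housekeeping genes (adjusted p = 0.261 and 0.0529), every probe for apoptosis and matrix genes (0.0522 and 0.0812), the mean of probes for iron handling (0.0802) and median scaling for housekeeping genes (0.0624). Apart from the estimated correlation, the unfolded protein response and interferon lists lost it only against protein-coding genes. The matrix list lost it without vehicle OGD 1 (adjusted p = 0.0593), and the housekeeping list without sham 2, sham 3 or vehicle OGD 3 (adjusted p = 0.0542, 0.0540 and 0.0569). HIF targets (adjusted p = 1.97e-06), histones (1.97e-06), replication (0.00600) and NF-kB genes (0.00136) passed against protein-coding genes alone, as did metallothioneins, which did not pass against all genes (0.0258).

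The lists that did not pass were pentose phosphate pathway (0 higher and 6 lower of 7), immediate early genes (4 and 15 of 21), metallothioneins (4 and 1 of 9), the ATF4 amino acid response (7 and 17 of 29), JumonjiC histone demethylases (3 and 6 of 12), HIF pathway components (2 and 5 of 9) and p53 targets (6 and 11 of 18). Cytosolic ribosomal proteins (7 and 12 of 30), proximal tubule (6 and 6 of 16), angiogenic factors (3 and 6 of 10), leukocyte (3 and 2 of 7) and podocyte markers (2 and 1 of 5) did not pass either. Their adjusted p ran from 0.0511 for pentose phosphate to 0.755 for angiogenic factors, and adjusted over the list alone the counts differed only for ATF4 (18 lower) and demethylases (7 lower). The proximal tubule list had its median at −0.15 although camera's direction was up, and angiogenic factors had a median of −0.31 and a mean of 0.20. Within the ATF4 list DDIT3, ASNS and TRIB3 were higher by 0.42 ± 0.06, 0.42 ± 0.09 and 0.64 ± 0.06 (adjusted p = 0.000247, 0.00427 and 3.43e-05), and at −0.94, −0.95 and −0.73 with spike-in scaling. Fibroblast markers (1 higher and 1 lower of 4), endothelial markers (2 and 0 of 2) and distal nephron markers (1 and 2 of 3) were too few to test.

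In all, 16773 of 23278 genes differed between vehicle OGD and sham (72.1%), with 7247 higher and 9526 lower, and 2912 and 2284 of these by at least 2-fold. The groups did not overlap for 75.6% of genes, against 10% by chance. With spike-in scaling 750 genes were higher and 20204 lower, and among protein-coding genes alone 2916 were higher and 8303 lower. Without a filter on dim probes 19361 were higher and 9512 lower, of 43308 genes, and with normexp background correction and quantile normalization 1041 genes changed by at least 2-fold. Of 5315 genes with several probes, 1116 (21%) had probes called in opposite directions. The gene named by a probe is therefore not always the gene that changed as a whole.

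The 8 largest rises measured in both groups were RNVU1-18 (5.23 ± 0.16), KRT79 (4.85 ± 0.48), LRRC2 (4.80 ± 0.44), GPR179 (4.74 ± 0.46), ACKR5 (4.43 ± 0.49), CD86 (4.38 ± 0.43), DDRGK1 (4.31 ± 0.12) and RPA4 (4.23 ± 0.37), with adjusted p of at most 8.15e-05. The probes of KRT79, LRRC2, GPR179, ACKR5, CD86 and RPA4 each held a run of 9 to 12 nt of alternating A and G, which few probes carry. Of the 195 kept probes with such a run of at least 8 nt, 148 rose and 25 fell, with a median of 2.80 (the plot of AG runs). RNVU1-18 (chromosome 14, 35016024 to 35016083) is a variant U1 RNA with near-identical copies, so the copy is uncertain. A second DDRGK1 probe was at −0.51. The largest bounds upward were PWRN1, at least 12-fold higher, GARNL3, at least 9.10-fold, and OR52E8, at least 8.68-fold. PWRN1 and OR52E8 also have probes with AG runs, of 13 and 9 nt, and a second GARNL3 probe was at −1.71.

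The 8 largest falls were EGR1, ZC3HAV1 (−4.53 ± 0.07), the small noncoding RNAs SNAR-D (−4.49 ± 0.09), SNAR-H (−4.43 ± 0.08), SNAR-G2 (−4.42 ± 0.10) and SNAR-B2 (−4.42 ± 0.08), the Cajal body RNA SCARNA22 (−4.24 ± 0.07) and the vault RNA VTRNA1-3 (−4.24 ± 0.14), with adjusted p of at most 6.59e-07. The SNAR genes are near-identical copies, so their probes are not independent. A second ZC3HAV1 probe was at −0.48. The largest bounds downward were NANOS1, at least 15.4-fold lower, EIF5, at least 12-fold, and ADAMTS5, at least 7.84-fold.

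**Figure D2:**
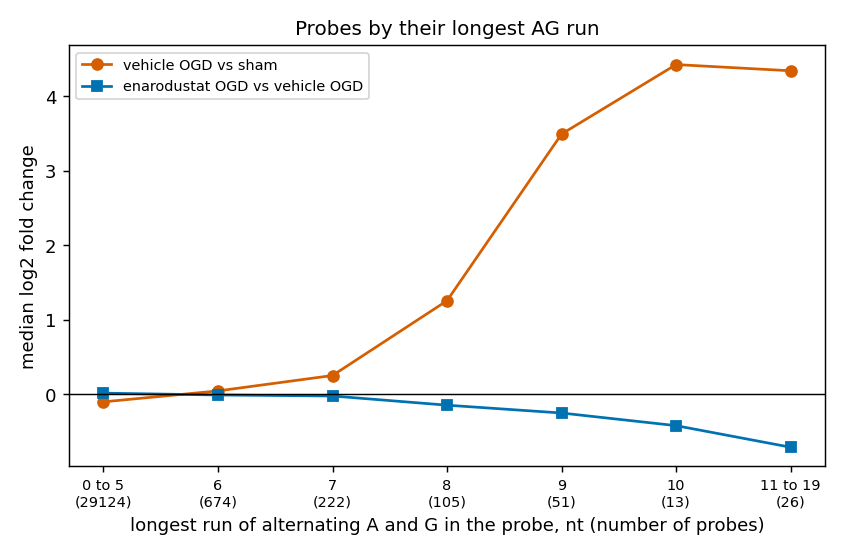
Median log2 fold change of probes (vertical) by the longest run of alternating A and G in the probe in nt (horizontal), for vehicle OGD against sham (circles) and enarodustat OGD against vehicle OGD (squares), with the number of probes under each class. For vehicle OGD against sham the median goes from −0.10 at 0 to 5 nt to 1.26 at 8 nt and 3.49 at 9 nt, while for enarodustat OGD against vehicle OGD it is −0.15 at 8 nt and −0.25 at 9 nt.

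Probes toward the 5′ end of a transcript rose against probes toward its 3′ end. Over 1437 pairs of probes at least 1000 nt apart, the 5′ probe shifted by 0.58 more than the 3′ probe in vehicle OGD against sham (median, log2). The shift was −0.02 over 825 pairs under 500 nt apart and 0.74 over 794 pairs at least 2000 nt apart. It was −0.12 for enarodustat OGD against vehicle OGD and 0.46 for enarodustat OGD against sham at 1000 nt or more. This shift and the lower signal relative to spike-ins move with the deprivation, as do the gene groups above.

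**Figure D3:**
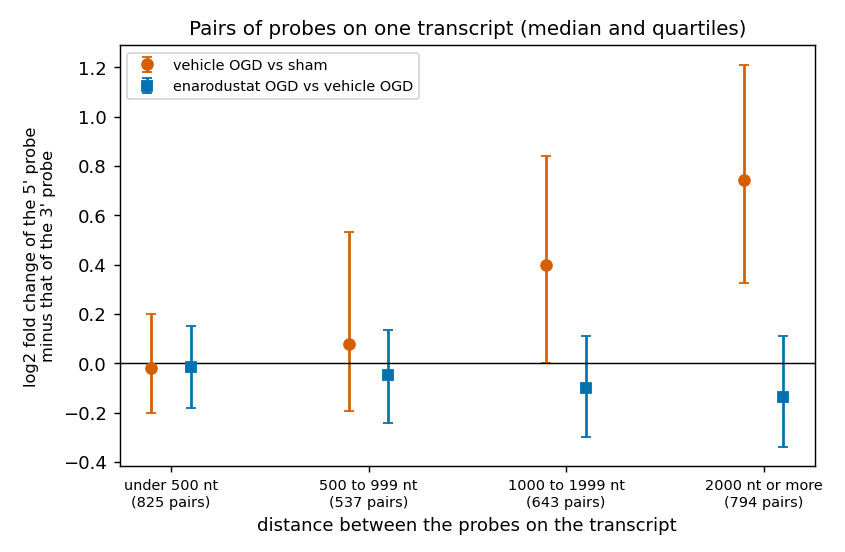
Median and quartiles of the log2 fold change of the 5′ probe minus that of the 3′ probe, for pairs of probes of 1 transcript by their distance in nt, for vehicle OGD against sham (circles) and enarodustat OGD against vehicle OGD (squares). For vehicle OGD against sham the median is −0.02 under 500 nt, 0.08 from 500 nt to under 1000 nt, 0.40 from there to under 2000 nt and 0.74 at 2000 nt or more.

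Enarodustat OGD was compared with vehicle OGD to see what pretreatment with the drug changed in deprived cells, the question in the series title. Enarodustat-pretreated cells had more mRNA of glycolytic genes and of other HIF targets. Of 21 glycolysis genes 20 were higher, with phosphoglycerate kinase PGK1 up by 1.38 ± 0.06 (adjusted p = 3.91e-06). Of 33 other HIF targets 29 were higher, with ANGPTL4, an inhibitor of lipoprotein lipase, up by 2.33 ± 0.06 (5.03-fold, adjusted p = 8.10e-07; chromosome 19, 8439197 to 8439256). CA9 was above background only with enarodustat, at least 8.78-fold higher (chromosome 9, 35677817 to 35679204).

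The glycolysis list stood 0.81 above all genes, with 20 higher and 1 lower, also adjusted over the list alone (adjusted p = 5.93e-11, and 0.199 with an estimated correlation). The glucose transporter SLC2A1 rose by 1.17 ± 0.06 (adjusted p = 1.64e-05), PDK1 by 1.11 ± 0.07 (adjusted p = 2.14e-05) and triosephosphate isomerase TPI1 by 1.1 ± 0.07 (adjusted p = 3.44e-05). LDHA rose by 0.92 ± 0.08, HK2 by 0.88 ± 0.12 (2.32 at its other probe) and PFKFB4 by 0.69 ± 0.07 (adjusted p = 0.000146, 0.00126 and 0.000243). The gene that fell was PFKM, the muscle isoform of phosphofructokinase, named after its values were seen, at −0.16 ± 0.05 (adjusted p = 0.0338), or 0.24 with spike-in scaling. Its call was lost when any 1 array of these 2 groups was left out (adjusted p = 0.0531 to 0.0935), with replicates as a block (0.0633) and with only the 6 arrays compared (0.0958). None of 10000 random lists matched on signal level had a median as high as the 0.83 of glycolysis or the 1.12 of HIF targets, the highest being 0.32 and 0.30.

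HIF targets outside glycolysis stood 1.1 above all genes, with 29 higher and 2 lower, also adjusted over the list alone (adjusted p = 7.88e-17, and 0.115 with an estimated correlation). FAM162A rose by 1.93 ± 0.07, BNIP3 by 1.85 ± 0.06 and ADM by 1.80 ± 0.06 (adjusted p = 1.63e-06, 1.14e-06 and 1.63e-06). VEGFA rose by 1.07 ± 0.08 (adjusted p = 5.93e-05), or 1.67 at its other probe, and EGLN3 by 1.02 ± 0.13 (adjusted p = 0.000754). Of the HIF pathway components 6 of 9 rose and 0 fell, also adjusted over the list alone, 0.48 above all genes (adjusted p = 0.0374, and 0.238 with an estimated correlation). EPAS1, which encodes HIF-2 alpha, rose by 0.64 ± 0.07, VHL, its ubiquitin ligase subunit, by 0.63 ± 0.09 and EGLN1, the enzyme PHD2, by 0.50 ± 0.08, with adjusted p of at most 0.00219. That list lost its call against protein-coding genes alone (adjusted p = 0.0585), without vehicle OGD 1 (adjusted p = 0.128) and under 7 other alternatives. Of the angiogenic factors 7 of 10 rose and 2 fell, also adjusted over the list alone, 0.40 above all genes (adjusted p = 0.0144, and 0.273 with an estimated correlation), a call lost with spike-in scaling. FGF2, fibroblast growth factor 2, rose by 0.60 ± 0.06 (adjusted p = 0.000395), or 1.5 at its other probe. Of 12 JumonjiC histone demethylases, oxygen-dependent enzymes, 8 rose and 0 fell, or 9 adjusted over the list alone, 0.31 above all genes (adjusted p = 0.00191, and 0.199 with an estimated correlation), with KDM4B at 0.66 ± 0.06, KDM3A at 0.64 ± 0.06 and KDM5B at 0.48 ± 0.06.

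Glycogen genes had 9 higher and 4 lower of 22, or 11 and 5 adjusted over the list alone, and the list did not pass (0.13 above all genes, adjusted p = 0.209, and 0.586 with an estimated correlation). It passed without a filter on dim probes (adjusted p = 0.0207). GYS1 rose by 1.21 ± 0.06 (2.31-fold, adjusted p = 9.58e-06), PGM1, a phosphoglucomutase, by 0.96 ± 0.06, PPP1R3C by 0.95 ± 0.06 and GBE1 by 0.94 ± 0.07 (adjusted p = 2.53e-05, 3.97e-05 and 7.20e-05).

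**Figure D4:**
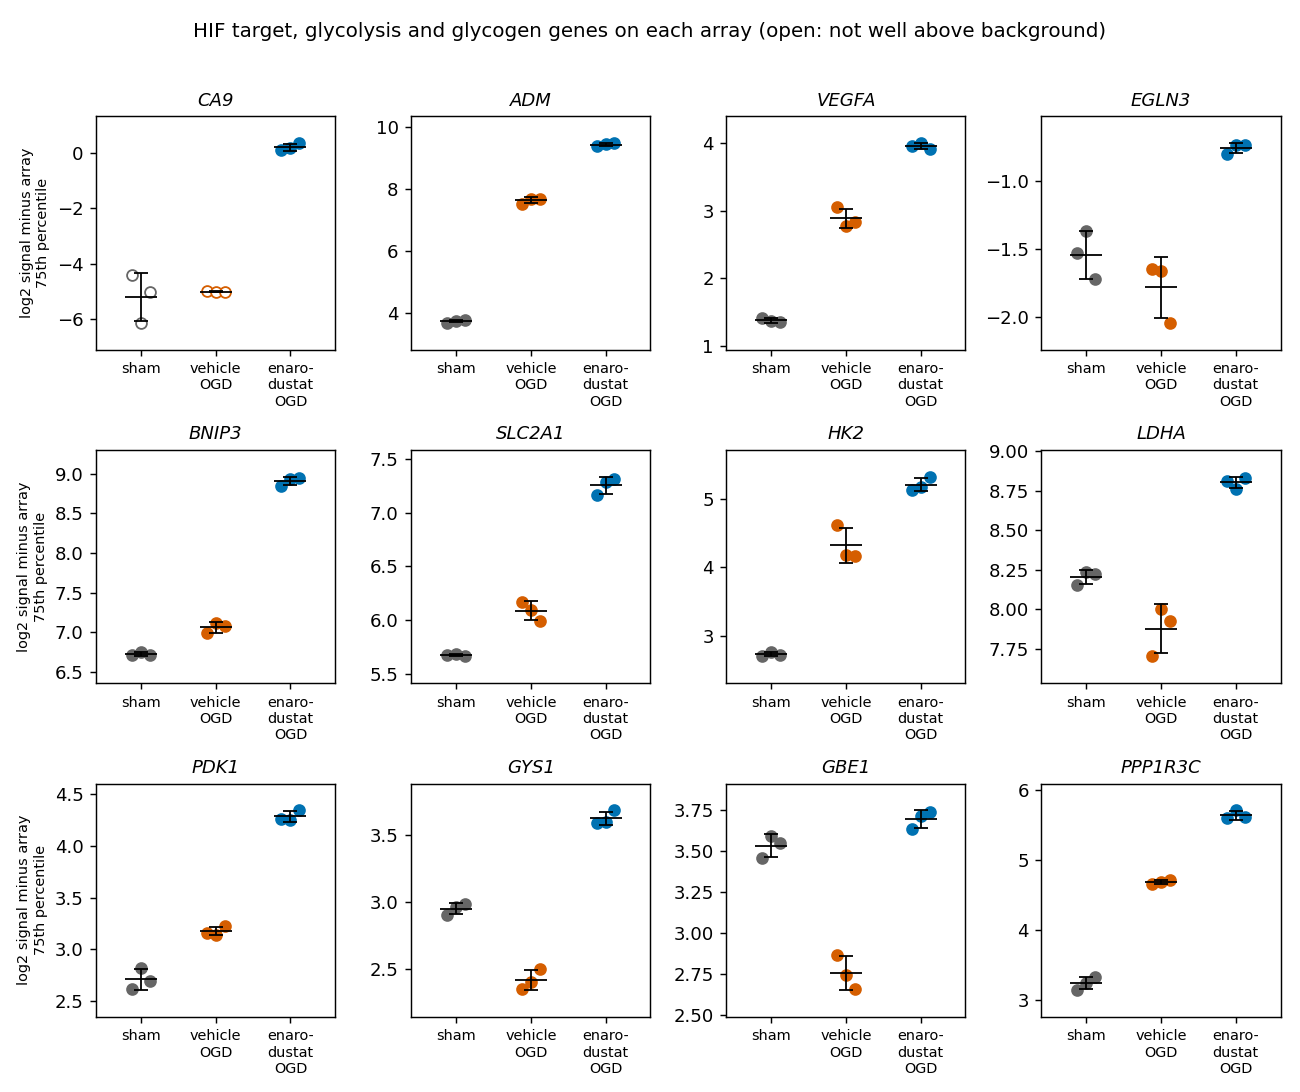
Signal of 12 HIF target, glycolysis and glycogen genes on each array, as log2 signal minus the array's 75th percentile, with 1 point per array, the mean and SD of 3 arrays as bars, and open points where the probe was not well above background. CA9 was above background on the enarodustat OGD arrays only, and GYS1 and GBE1 were lower in vehicle OGD than in sham and higher with enarodustat than in vehicle OGD, and both remained so with spike-in scaling.

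NF-kB signalling genes had 15 higher and 0 lower of 19, also adjusted over the list alone, 0.48 above all genes (adjusted p = 1.11e-05, and 0.199 with an estimated correlation). The chemokines CXCL8, CCL20 and CXCL1 rose by 1.74 ± 0.09, 1.34 ± 0.08 and 0.71 ± 0.05, and TNFAIP3 by 1.51 ± 0.06, with adjusted p of at most 6.63e-05. Metallothioneins, metal-binding proteins, had 5 higher and 1 lower of 9, or 6 and 1 adjusted over the list alone, 0.33 above all genes (adjusted p = 0.0144, and 0.342 with an estimated correlation), with MT1H at 1.76 ± 0.12, MT1M at 0.99 ± 0.07 and MT1X at 0.70 ± 0.06. Immediate early genes had 10 higher and 3 lower of 21, or 11 and 3 adjusted over the list alone, 0.28 above all genes (adjusted p = 0.0184, and 0.342 with an estimated correlation), a call lost with spike-in scaling (adjusted p = 0.0580) and at the probes nearest the 5′ end (adjusted p = 0.0664). DUSP6 and DUSP5, phosphatases of ERK, rose by 1.34 ± 0.09 and 0.87 ± 0.07, and IER3 by 0.98 ± 0.05. In the unfolded protein response 7 of 20 rose and 1 fell, or 9 and 1 adjusted over the list alone, 0.14 above all genes (adjusted p = 0.0257, and 0.342 with an estimated correlation), with EDEM1 at 0.72 ± 0.07 and SEL1L, both of the degradation of misfolded proteins, at 1.31 ± 0.08, or −0.38 at another of its probes, with no call for the mean of its probes. That list lost its call without vehicle OGD 2 (adjusted p = 0.0550) and under 4 other alternatives. In autophagy and lysosome genes 12 of 26 rose and 2 fell, also adjusted over the list alone, 0.20 above all genes (adjusted p = 0.0257, and 0.511 with an estimated correlation), with ATG14 at 0.95 ± 0.10 and GABARAPL1 at 0.40 ± 0.05, a call lost without vehicle OGD 1 (adjusted p = 0.0575) and under 6 other alternatives. Heat shock genes lay 0.33 below all genes, with 9 of 13 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.00724, and 0.199 with an estimated correlation). HSPA1A and HSPA1B, near-identical HSP70 genes whose probes are uncertain between them, fell by 1.51 ± 0.12 and 1.56 ± 0.17, DNAJA1 by 0.91 ± 0.05 and DNAJB1 by 0.69 ± 0.08. With spike-in scaling 4 heat shock genes were lower and 4 higher (median 0.09). Ribosome biogenesis had 10 of 25 lower and 1 higher, or 12 and 1 adjusted over the list alone, 0.23 below all genes (adjusted p = 0.000693, and 0.273 with an estimated correlation), a call lost with spike-in scaling, where 1 was lower and 12 higher (median 0.19). NOP58 and NOP56, proteins of box C/D particles, fell by 0.67 ± 0.05 and 0.39 ± 0.05, with NOP56 at 0.02 under spike-in scaling and its call lost at the probe nearest the 5′ end (−0.23, adjusted p = 0.124), and RRS1 fell by 0.51 ± 0.07, a call lost with that scaling (adjusted p = 0.165).

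The other lists did not pass, with adjusted p from 0.0948 to 0.995. Among these, tricarboxylic acid cycle genes had 4 higher and 0 lower of 19, oxidative phosphorylation 2 and 1 of 35, pentose phosphate pathway 0 and 0 of 7, fatty acid oxidation 3 and 4 of 20 and cholesterol synthesis 8 and 2 of 24. The ATF4 amino acid response had 11 and 4 of 29, NRF2 antioxidant genes 6 and 1 of 19, iron handling 6 and 1 of 12, p53 targets 6 and 1 of 18, apoptosis regulators 5 and 0 of 21 and interferon response 3 and 3 of 22. Replication had 3 and 5 of 26, G2/M 6 and 5 of 25, histones 5 and 2 of 15, cytosolic ribosomal proteins 1 and 4 of 30, and housekeeping genes 6 and 2 of 14. Tubular injury had 5 and 1 of 15, matrix and TGF-beta response 6 and 2 of 22, proximal tubule 2 and 1 of 16, leukocyte markers 1 and 1 of 7, and podocyte markers 2 and 0 of 5. Fibroblast (1 and 0 of 4), endothelial (0 and 0 of 2) and distal nephron markers (1 and 0 of 3) were too few to test. Oxidative phosphorylation passed as lower than all genes with quantile normalization, normexp and the series table (adjusted p = 0.0475, 0.0319 and 0.0173). Cytosolic ribosomal proteins passed with spike-in scaling (adjusted p = 0.0184), with camera's direction turned and their shift from all genes unchanged. Adjusted over the list alone, the counts became 7 and 1 for the tricarboxylic acid cycle, 1 and 0 for oxidative phosphorylation, 8 and 3 for cholesterol, 12 and 4 for ATF4, 7 and 2 for p53, 4 and 0 for apoptosis, 0 and 4 for ribosomal proteins, 7 and 2 for matrix, and 7 and 3 for both histones and housekeeping. Median, mean and camera differed in sign for fatty acid oxidation, replication, G2/M, cytosolic ribosomal proteins and proximal tubule, all with medians between −0.02 and 0.03. TRIB3, DDIT3 and HMOX1 rose by 0.74 ± 0.06, 0.28 ± 0.06 and 0.85 ± 0.13 (adjusted p = 0.000109, 0.00712 and 0.00198). ASNS was at −0.08 ± 0.09 and HAVCR1 at −0.15 ± 0.07 (adjusted p = 0.549 and 0.125), and both were positive with spike-in scaling, at 0.32 and 0.25.

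In all, 8361 of 23278 genes differed between enarodustat OGD and vehicle OGD (35.9%), with 4784 higher and 3577 lower, and 635 and 266 of these by at least 2-fold. With normexp background correction and quantile normalization 158 and 18 changed by at least 2-fold, and 182 in all with the series table. The groups did not overlap for 48.5% of genes, against 10% by chance. With spike-in scaling 14297 genes were higher and 624 lower, and without a filter on dim probes 4760 were higher and 10295 lower. Among genes with several probes, 225 of 5315 (4.23%) had probes called in opposite directions. The groups lay on different slides, so slide and drug cannot be told apart by the design, and the spike-in probes give only a measure of what a slide does to all probes alike.

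The 8 largest rises measured in both groups were NACA4P (2.74 ± 0.07), CAV3 (2.61 ± 0.08), ZNF90 (2.47 ± 0.09, with other probes down to −0.06), NOG (2.45 ± 0.11), TMEM178A (2.39 ± 0.07), ANGPTL4, SLC5A12 (2.31 ± 0.23) and CEACAM20 (2.30 ± 0.10), with adjusted p of at most 0.000258. NOG, an antagonist of BMP, has a probe with a run of 9 nt of alternating G and T. The 8 largest falls were MIR205HG (−1.73 ± 0.15, with other probes up to −1.02), EFS (−1.61 ± 0.23), HSPA1B, PSMB11 (−1.54 ± 0.19, with its other probe at 0.83, and no call for their mean), RNVU1-18 (−1.52 ± 0.16), HSPA1A, PPARGC1B (−1.44 ± 0.17) and MYH3 (−1.34 ± 0.13), with adjusted p of at most 0.00147. The largest bounds upward after CA9 were CRIM1, at least 5.46-fold higher, and RNF113B, at least 4.63-fold. Downward they were CCDC170, at least 2.20-fold lower, PPARA, at least 2-fold, with its other probe at 0.00, and SNORA52, at least 1.85-fold. PPARA and SNORA52 lost their calls with the series table (adjusted p = 0.167 and 0.248).

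Enarodustat OGD was compared with sham to show where the cells stood after both steps. HIF targets were far above sham, with ADM higher by 5.70 ± 0.06 (52.0-fold, adjusted p = 8.03e-09) and HILPDA by 4.46 ± 0.07 (adjusted p = 1.55e-08). Of 21 glycolysis genes 17 were higher than sham, with SLC2A3 up by 2.80 ± 0.11 (adjusted p = 3.60e-07) and by 3.83 at its other probe. With spike-in scaling 6 of the 21 were higher and 13 lower, with a median of −0.41 instead of 0.56. Replication, ribosome biogenesis and heat shock genes were lower than sham, with DNAJA1 down by 2.61 ± 0.05 (adjusted p = 3.62e-08). This comparison shares its arrays with the other 2 and is not independent of them.

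HIF targets outside glycolysis had 30 of 33 higher and 2 lower, also adjusted over the list alone, 1.87 above all genes (adjusted p = 8.61e-11, and 0.228 with an estimated correlation). ANKRD37 was higher by 3.34 ± 0.07 and NDRG1 by 2.97 ± 0.07, VEGFA by 2.58 ± 0.08, BNIP3 by 2.18 ± 0.06 and EGLN3 by 0.78 ± 0.13, all with adjusted p of at most 0.000672. With spike-in scaling 21 were higher and 9 lower (median 0.89), and EGLN3 was at −0.18. CA9 was at least 19.5-fold higher. Glycolysis had 17 higher and 2 lower of 21, also adjusted over the list alone, 0.58 above all genes (adjusted p = 0.000308, and 0.421 with an estimated correlation). HK2 was higher by 2.46 ± 0.12 (4.83 at its other probe), ENO2 by 2.07 ± 0.09, SLC2A1 and PDK1 each by 1.58, PFKFB4 by 1.31 ± 0.07 and LDHA by 0.60 ± 0.08, with adjusted p of at most 0.000250, and LDHA stood at −0.37 with spike-in scaling. Glycogen genes had 8 higher and 7 lower of 22, also adjusted over the list alone, without passing (adjusted p = 0.592, and 0.760 with an estimated correlation). PPP1R3C was higher by 2.40 ± 0.06 and GYS1 by 0.67 ± 0.06 (adjusted p = 7.87e-08 and 2.36e-05), and GBE1 was at 0.16 ± 0.07 (adjusted p = 0.0685). With spike-in scaling GYS1 was at −0.29 and GBE1 at −0.80.

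NF-kB signalling genes had 16 higher and 3 lower of 19, also adjusted over the list alone, 0.98 above all genes (adjusted p = 0.000224, and 0.287 with an estimated correlation), with TNFAIP3 at 3.52 ± 0.06, BIRC3 at 1.85 ± 0.08 and CXCL1 at 1.31 ± 0.05. With spike-in scaling 7 were higher and 6 lower (median 0.00). Histones had 12 higher and 2 lower of 15, also adjusted over the list alone, 1.1 above all genes (adjusted p = 0.000720, and 0.291 with an estimated correlation), with H2BC21 at 2.47 ± 0.09 and H2BC4 at 1.81 ± 0.07. With spike-in scaling 7 were higher and 5 lower (median 0.12). Metallothioneins had 7 higher and 0 lower of 9, or 8 adjusted over the list alone, 0.63 above all genes (adjusted p = 0.00230, and 0.329 with an estimated correlation), with MT1H at 1.63 ± 0.12 and MT1M at 1.28 ± 0.07, a call lost with spike-in scaling, where 2 were higher and 6 lower (median −0.35). Replication had 23 lower and 0 higher of 26, also adjusted over the list alone, 0.54 below all genes (adjusted p = 1.50e-05, and 0.287 with an estimated correlation), with CDT1 at −1.1 ± 0.06 and RFC4, a subunit of the clamp loader, at −1.05 ± 0.06. Ribosome biogenesis had 21 lower and 1 higher of 25, also adjusted over the list alone, 0.48 below all genes (adjusted p = 0.000107, and 0.287 with an estimated correlation), with RRS1 at −1.74 ± 0.07 and NOP56 at −1.35 ± 0.05. Heat shock genes had 12 lower and 0 higher of 13, or 13 lower adjusted over the list alone, 0.61 below all genes (adjusted p = 0.000515, and 0.228 with an estimated correlation), with DNAJB1 at −2.36 ± 0.08. These 8 lists passed against protein-coding genes alone, with adjusted p of at most 0.0177.

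A further 6 lists lay below all genes but lost the call against protein-coding genes alone (adjusted p = 0.109 to 0.337). Oxidative phosphorylation had 24 lower and 2 higher of 35, fatty acid oxidation 17 and 1 of 20, interferon response 16 and 2 of 22, G2/M 16 and 1 of 25, cholesterol synthesis 17 and 2 of 24, and the tricarboxylic acid cycle 14 and 1 of 19. They passed with adjusted p from 0.00255 to 0.0284, against adjusted p from 0.287 to 0.570 with an estimated correlation. Adjusted over the list alone, interferon response had 17 lower and the tricarboxylic acid cycle 15, and the other counts were the same. The tricarboxylic acid cycle list lost its call without enarodustat OGD 1 (adjusted p = 0.0583) and with median scaling (adjusted p = 0.0630). G2/M, cholesterol synthesis and the tricarboxylic acid cycle lost theirs with quantile normalization (adjusted p = 0.164 to 0.243, with shifts of −0.15, −0.13 and −0.13), with normexp and quantile normalization (adjusted p = 0.136 to 0.236) and with the series table (adjusted p = 0.135 to 0.247), and cholesterol synthesis also with every probe (adjusted p = 0.0533).

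The remaining lists did not pass, with adjusted p from 0.0741 for pentose phosphate to 0.962 for proximal tubule, and with the same counts adjusted over the list alone. Pentose phosphate had 0 higher and 6 lower of 7, ATF4 9 and 16 of 29, unfolded protein response 4 and 12 of 20, NRF2 4 and 12 of 19, immediate early genes 6 and 11 of 21, and p53 targets 6 and 10 of 18. Apoptosis regulators had 5 and 13 of 21, autophagy 6 and 13 of 26, cytosolic ribosomal proteins 7 and 13 of 30, iron handling 2 and 7 of 12 and housekeeping genes 2 and 6 of 14. Tubular injury had 4 and 10 of 15, matrix 5 and 13 of 22, angiogenic factors 5 and 3 of 10, demethylases 6 and 3 of 12, HIF pathway components 5 and 3 of 9, proximal tubule 5 and 7 of 16, leukocyte 4 and 2 of 7 and podocyte markers 4 and 1 of 5. Fibroblast (1 and 1 of 4), endothelial (2 and 0 of 2) and distal nephron markers (1 and 1 of 3) were not tested. TRIB3, DDIT3 and ASNS were higher by 1.38 ± 0.06, 0.71 ± 0.06 and 0.34 ± 0.09 (adjusted p = 6.70e-07, 1.45e-05 and 0.0121), with DDIT3 at −0.26 and ASNS at −0.63 under spike-in scaling. HAVCR1 was at −0.84 ± 0.07 (adjusted p = 1.36e-05), and HMOX1 at 0.29 ± 0.13 (adjusted p = 0.0767), or −0.68 with spike-in scaling.

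In all, 16604 of 23278 genes differed between enarodustat OGD and sham (71.3%), with 7937 higher and 8667 lower, and 2836 and 2314 of these by at least 2-fold. With normexp background correction and quantile normalization 764 and 473 changed by at least 2-fold, and 1292 in all with the series table. The groups did not overlap for 77.8% of genes, against 10% by chance. With spike-in scaling 1648 genes were higher and 17667 lower, and among protein-coding genes alone 3272 were higher and 7603 lower. Without a filter on dim probes 18600 were higher and 8790 lower. The 8 largest rises measured in both groups were ADM, HILPDA, NOG (4.41 ± 0.11), KRT79 (4.26 ± 0.48), GPR179 (4.23 ± 0.46), ACKR5 (4.20 ± 0.49), LRRC2 (4.19 ± 0.44) and PDE4DIP (4.16 ± 0.12, with other probes down to −0.25). KRT79, GPR179, ACKR5 and LRRC2 have the AG-run probes described above. The 8 largest falls were SNAR-D (−5.26 ± 0.09), SNAR-B2 (−5.21 ± 0.08), SNAR-H (−5.20 ± 0.08), ZC3HAV1 (−5.18 ± 0.07, with its other probe at 0.04), SNAR-G2 (−5.14 ± 0.10), EGR1 (−4.68 ± 0.18), SCARNA22 (−4.63 ± 0.07) and SCARNA20 (−4.58 ± 0.16). All 16 had adjusted p of at most 0.000113. The largest bounds after CA9 were CRIM1, at least 12.1-fold higher, PWRN1, at least 10.7-fold, with its AG-run probe, and, downward, SNORA12, at least 29.6-fold lower, VTRNA1-3, at least 29.1-fold, and EIF5, at least 15.3-fold. Probes of 1 gene were called in opposite directions for 1043 of 5315 genes (19.6%).

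Across genes, the change with deprivation and the change with enarodustat correlated at r = −0.195, with a covariance of −0.0850. Both use the vehicle OGD arrays, which alone gave r = −0.500 and a covariance of −0.0144 over 100 simulations with no effect, a difference of covariances of −0.0706. Genes are not independent replicates, so no p is given. Of genes that fell with deprivation, 2484 rose with enarodustat, against 1958 for independent lists, and 1155 fell, against 1464. Of genes that rose with deprivation, 1814 fell with enarodustat, against 1114, and 1059 rose, against 1489. With 3 vehicle OGD arrays the shared group could not be divided into parts of at least 2 arrays each, so part of the excess may come from the shared arrays.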

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

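All tests in this part, with the limits they were read by, were set after the results they bear on had been seen. DCP control spots, which the comparisons do not use, had a median unscaled signal 1.2378 times that of sham in vehicle OGD and 1.2994 times that of sham in enarodustat OGD. The spike-in probes were also above sham, by 0.19 in vehicle OGD and 0.31 in enarodustat OGD (unscaled log2). Part of the DCP rise is therefore shared with them.

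Of the 10 ways to split the 6 arrays of a comparison into groups of 3, the real one alone called as many genes in vehicle OGD against sham (1 split, 16773 genes, highest other 0), in enarodustat OGD against vehicle OGD (1 split, 8361 genes, highest other 1) and in enarodustat OGD against sham (1 split, 16604 genes, highest other 0). For gene lists the counts were 20 with the highest other at 8 (1 split), 12 with the highest other at 7 (1 split) and 14 with the highest other also at 14 (2 splits). With 10 splits the share cannot fall under 0.05, which is too few. Every other split also mixes arrays of both real groups. The real difference then enters the spread, so few gene calls could be made in those splits whatever the data. For lists, the other splits keep part of the real difference. Neither count therefore measures chance.

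HIF target and glycolysis genes were higher with enarodustat than with vehicle after deprivation. Scaling by a percentile, the median or the spike-ins subtracts the same amount from every probe of an array. Such scalings cannot change a shift relative to all genes, so they do not test the normalization. Quantile normalization, normexp with quantile normalization and the series table can change it, though the series table closely followed the normexp values. The lowest shift of either list relative to all genes over 6 scalings was 0.66935 (log2). The normalization is argued against only as far as the scalings that can change the shift test it. The signal level of the list members is argued against too, since 0 of 10000 random lists matched on level had a median as high. An effect of slide and scan alike for all probes would cancel in a shift relative to all genes, so the spike-in probes cannot test it here. They differed between the 2 slides by at most 0.23657 (unscaled log2). An effect that differs between probes cannot be told apart from the drug, because 0 slides held both enarodustat and vehicle arrays. A difference that goes with probe sequence was present between these groups, in probes with GT runs (given below), and its source was not tested. Inhibition of the prolyl hydroxylases by enarodustat may be a cause, and that stays open with such an effect of the slide.

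Probes near the 5′ end of transcripts rose over probes near the 3′ end after deprivation. Compression of dim probes by background is argued against as the whole cause by pairs in which both probes were bright (4-fold over the 75th percentile). Their median shift was 0.54102 over 187 pairs. A stricter limit of 16-fold, tried first, left 32 pairs with a median of 0.42 and a lower quartile of 0.00. With normexp and quantile normalization the shift of the 1437 pairs at least 1000 nt apart was 0.32, against 0.58, so its size depends on the processing. GC content is argued against by pairs whose 5′ probe was lower in GC, with a median of 0.50695. A positive shift in 89.924% of pairs at least 2000 nt apart is consistent with longer labelled products from every transcript, which remains a hypothesis. Earlier transcript ends or decay from the 3′ end were not tested, and no biological explanation was tested.

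Probes with a run of at least 8 nt of alternating A and G rose after deprivation, by a median of 2.80 over 195 probes. In the 62 of their genes with other probes, the AG-run probes had a median of only 0.75 and the others 0.02, a median difference within a gene of 0.69587 (quartiles 0.18 and 2.38), which argues there against higher transcription of the probe's own gene as the whole cause, by a bound (a lower quartile above 0) set after these values were seen and in place of an earlier one; for the 133 AG-run probes with no other probe this stays open. A rise of repeats of any kind is argued against, since the highest median among probes with CT, AC, GT or AT runs was 0.27581. The vehicle OGD arrays fell in 1 order for 74.872% of the AG-run probes, against 17% of other probes of the same level. That order was picked as the most frequent among the AG-run probes. Their median SD within vehicle OGD was 0.71, against 0.12 for the others, so the 2 sets are unlike. Probes that vary together for any reason would share an order, so this does not decide the source. That 1 labelled product is shared by these probes is a hypothesis, the product was not identified, and no other biological explanation was tested.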

How the results depend on the processing

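The probes nearest the 3′ or 5′ end, protein-coding genes only and the omission of AG-run probes were alternatives chosen after the results were seen, and the check of pairing was not planned either. Where no cause is named, the cause was not tested. A value was counted as reversed only where its direction turned and it passed at first or under the alternative. Of the values for named genes under alternatives 4526 neither reversed in this sense nor crossed the threshold, 25 reversed, 21 gained a call and 20 lost it. A direction that turned with no call on either side is counted among the unchanged. For lists the numbers were 2268, 8, 100 and 171. The signal limits what could be tested: 48.2 to 55.3% of spots were above background.

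Lists passing numbered 0, 0 and 0 with an estimated correlation and 31, 24 and 31 with fry, in the order vehicle OGD against sham, enarodustat OGD against vehicle OGD, enarodustat OGD against sham. In vehicle OGD against sham 10 passed with quantile normalization, 11 with normexp, 11 with the series table, 10 with a filter on all 9 arrays (19112 genes tested) and 5 against protein-coding genes only. In enarodustat OGD against vehicle OGD 23 passed with no filter on dim probes. In enarodustat OGD against sham 26 passed with no filter and 8 against protein-coding genes only. Leaving out 1 array gave 19 to 20, 10 to 12 and 13 to 14 lists.

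With no filter 28873, 15055 and 27390 genes changed in the 3 comparisons, of 43308 tested. With spike-in scaling 14921 changed in enarodustat OGD against vehicle OGD, and among protein-coding genes only, with fewer genes tested, 10875 changed in enarodustat OGD against sham. Leaving out 1 array gave 15432 to 16522, 6280 to 8116 and 15273 to 15898 genes. Leaving out AG-run probes gave 16650, 8377 and 16477.

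In enarodustat OGD against vehicle OGD, an estimated correlation gave shifts of 0.80705 for glycolysis (adjusted p = 0.199) and 1.1012 for HIF targets (adjusted p = 0.115). Glycogen genes passed with no filter (shift 0.26792, adjusted p = 0.0207). Fry, which tests a list against no change and not against other genes, gave adjusted p = 6.29e-05 for them; their shift from all genes, 0.1317, did not pass. The correlation between the deprivation and enarodustat changes was −0.16096 with normexp, −0.35558 with no filter, −0.11494 for protein-coding genes only, and −0.28045 to −0.15608 with 1 array left out.

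The direction given by fry was opposite to that of camera in vehicle OGD against sham for angiogenic factors (fry up, shift from all genes −0.22112) and podocyte markers (fry down, shift 0.35522), and in enarodustat OGD against sham for proximal tubule (fry up, shift −0.052281). These shifts are those of the report, since fry has none of its own. Oxidative phosphorylation reversed in enarodustat OGD against vehicle OGD with quantile normalization (−0.087784), normexp (−0.068016) and the series table (−0.067138). It then passed as lower than all genes (adjusted p = 0.0475, 0.0319 and 0.0173 with camera). With spike-in scaling the direction of camera turned for NF-kB genes in vehicle OGD against sham (shift from all genes 0.55212, the same as without that scaling). It also turned for cytosolic ribosomal proteins in enarodustat OGD against vehicle OGD (−0.016523), a list that then passed (adjusted p = 0.0184). Of these lists only NF-kB genes had passed at first. The median of protein-coding genes in enarodustat OGD against vehicle OGD turned to −0.0082712 with quantile normalization, −0.0061638 with normexp and −0.0026785 with the series table.

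Spike-in scaling shifts all genes of an array by 1 amount, and this reversed in vehicle OGD against sham ENO2 (−0.24929), BIRC3 (−0.24961), PDK1 (−0.90235), SLC2A1 (−0.95746), PFKFB4 (−0.75448), BNIP3 (−1.0319), DDIT3 (−0.94433), ASNS (−0.95273), TRIB3 (−0.73142) and MALAT1 (−0.34248). It reversed in enarodustat OGD against vehicle OGD PFKM (0.24375), NOP56 (0.015861), ASNS (0.32297) and HAVCR1 (0.25377), and in enarodustat OGD against sham EGLN3 (−0.18302), LDHA (−0.37213), GYS1 (−0.2936), GBE1 (−0.80487), DDIT3 (−0.26128), ASNS (−0.62976) and HMOX1 (−0.67871). The medians of SNORD (−0.27024), SNORA (−0.86102) and long noncoding genes (−0.98075) reversed with it in vehicle OGD against sham, long noncoding genes in enarodustat OGD against vehicle OGD (0.36427), and SNORD (−0.36921) and long noncoding genes (−0.53002) in enarodustat OGD against sham. In enarodustat OGD against vehicle OGD another probe was used, and reversed the gene, for PPARA with a filter on all 9 arrays (0.001863) and nearest the 5′ end (0.001863), for SEL1L nearest the 3′ end (−0.38204) and for PSMB11 nearest the 5′ end (0.82614).

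With the replicate number as a block 16582, 7702 and 16433 genes changed. By a limit of 0.1 the numbers did not pair the samples: deviations of arrays with the same number correlated at −0.061 to 0.077 across genes, 0 of 9 above it. Among arrays of other groups, 5 of 9 arrays correlated best with an array of their own number. Between sham and vehicle OGD, same-number pairs were at 0.059 to 0.077 and other pairs at −0.060 to −0.013. Same-number pairs with enarodustat OGD went both ways, from −0.061 to 0.028. A weak pairing of sham with vehicle OGD is therefore not excluded. A slide block could not be fitted for comparisons with enarodustat, and vehicle OGD against sham lies within 1 slide, where a model of its 6 arrays gave 16374 genes.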

Other observations

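Small noncoding RNAs were counted by class, and all tests in this part were chosen after the results were seen. In vehicle OGD against sham, 94 of 115 C/D box snoRNAs (SNORD) rose and 6 fell, with a median of 1.1 relative to the 75th percentile and −0.27 with spike-in scaling. Of 89 H/ACA box snoRNAs (SNORA) 45 rose and 28 fell, with a median of 0.51, or −0.86 with spike-in scaling. Of 20 Cajal body RNAs 5 rose and 10 fell (median −0.59, or −1.96 with spike-in scaling), of 10 snaR RNAs 2 rose and 6 fell (−4.16, or −5.53) and of 3 vault RNAs 0 rose and 2 fell (−3.01, or −4.38). Long noncoding RNAs had 2304 of 4634 higher and 522 lower (median 0.39, or −0.98 with spike-in scaling), and protein-coding genes 2820 of 14159 higher and 8155 lower (−0.35, or −1.72). NEAT1 and MALAT1, nuclear long noncoding RNAs, were higher by 3.13 ± 0.09 (adjusted p = 2.33e-07) and 1.03 ± 0.11 (adjusted p = 7.84e-05), with MALAT1 at −0.34 under spike-in scaling and its other probes from 0.15 to 1.52. The mRNAs KLF3 and PCF11 fell by 3.09 ± 0.15 and 2.64 ± 0.10 (adjusted p = 1.43e-06 and 5.63e-07). Many snoRNAs and snaR RNAs have near-identical copies, so the copy measured is uncertain. With normexp and quantile normalization the medians of SNORD, SNORA, Cajal body and vault RNAs were nearer 0, at 0.29, 0.09, −0.22 and −0.45.

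With enarodustat against vehicle after deprivation, 66 SNORD fell and 0 rose (median −0.46), 60 SNORA fell and 3 rose (−0.52), and 14 Cajal body RNAs fell and 1 rose (−0.59). With spike-in scaling most of this went, to 17 SNORD lower and 11 higher (median −0.06), 22 SNORA lower and 7 higher (−0.12) and 7 Cajal body RNAs lower and 1 higher (−0.19). With normexp and quantile normalization the medians were −0.17, −0.27 and −0.20. Long noncoding RNAs had 703 higher and 716 lower (median −0.04, or 0.36 with spike-in scaling). Against sham, enarodustat OGD had 69 SNORD higher and 8 lower (0.60, or −0.37 with spike-in scaling), and 36 SNORA higher and 41 lower (−0.26, or −1.23).

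Probes with runs of alternating G and T stood apart in enarodustat OGD against vehicle OGD. The median was 0.01 for runs of 0 to 7 nt, 0.21 for 8 to 9 nt (45 higher and 15 lower of 125), 0.86 for 10 to 11 nt (32 and 0 of 46) and 1.08 for 12 to 31 nt (37 and 0 of 37). In vehicle OGD against sham the longest class had a median of −0.40, with 0 higher and 30 lower, and in enarodustat OGD against sham 0.59, with 37 higher and 0 lower. The enarodustat OGD arrays lay on a slide of their own, so slide and drug cannot be told apart for these probes either. No explanation was tested.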
